A study of Mus musculus with 39 samples.

How the data were processed

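Cortical bone RNA of mouse femurs was measured by single-end RNA sequencing on a BGISEQ500 instrument, per the submitters' design text. The design text counts 6 WT, 8 Sik2/3 DKO, 11 WT and 12 col1a1-Pth1r H223R samples, while the labels of the libraries give 8 WT libraries for the Sik2/3 experiment, and all 39 labelled libraries were used. Soft tissue was removed and epiphyses were trimmed off, per the labels' protocols. The design text says that marrow was not flushed from the bones of the C1HR experiment, whereas the extraction protocol attached to every library says that it was, and the text here takes neither as settled. RNA integrity numbers were above 8, per the design text. Another model that the design text names, treatment with an antibody to sclerostin, was not analysed here.

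Reads were mapped by the authors with STAR to the mm9 mouse genome with Ensembl annotation, per the design text, with neither the STAR version nor the annotation release stated. The deposited values are counts per gene from HTSeq 0.6.0, without strand per the file names. Each library has 37583 genes and 5 tallies of unassigned reads. The design text calls these values CPM, but they are whole numbers with totals that differ between libraries, so they were used as raw counts. The criterion of the submitters was an edgeR false discovery rate under 0.05 with more than a 2-fold change, per the design text. Gene names, coordinates and exon overlaps came from GENCODE vM1 on NCBIM37, the assembly that mm9 names, and 37168 gene identifiers matched it while 415 did not. The unmatched Ahsp left the erythroid list with 14 of 15 members, and 0 of 10 mitochondrially encoded genes were in the files, so that list has no result. In counting without strand, reads that match exons of more than 1 gene are tallied as ambiguous and count for neither gene. Exons of 11 of 89 named genes overlap another annotated gene, Sik2, Col1a1, Csf1r and Runx2 among them.

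Gene counts per library ranged from 11444686 to 24922490. Reads that did not map uniquely made up a median of 30.8% of reads in the libraries labelled DKO, 26.8% in those labelled WT, 29.7% in C1HR and 48.7% in its WT group. Chi-square per degree of freedom between pairs of libraries of a group had medians of 67.7, 59.4, 47.8 and 14.7 in the same order, over genes with a summed count above 20, so no group varied by counting noise alone. PCR reads without molecular identifiers are not independent molecules.

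Counts were analysed with R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and summaries and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. In each experiment alone, genes were kept by filterByExpr (minimum count 10, minimum total 15), libraries were scaled by TMM, dispersions were estimated, and the groups were compared with edgeR's quasi-likelihood test with robust estimation. Adjusted p are Benjamini-Hochberg values from that test unless another tool is named, and CPM are from the computed TMM library sizes with a prior count of 2 for log2 values. The difference of the effects was a contrast in 1 fit of all 4 groups. Genes past both thresholds in both comparisons were counted by direction beside the number that independent lists would share, and log2 fold changes were correlated across genes.

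The comparisons, tests, alternatives, gene lists and the rule for naming genes were fixed before the data were examined. The lists were osteoblast, osteocyte, osteoclast, secreted factors that regulate osteoclasts, cAMP and CREB-CRTC target genes, Wnt targets and antagonists, fibrillar and pericellular matrix, matrix proteases and inhibitors, cell cycle, erythroid, granulocyte, B lineage, T and NK cell, megakaryocyte, macrophage, adipocyte, skeletal muscle, cartilage, endothelial, marrow stromal and skeletal progenitor, interferon-stimulated, immediate early and stress, unfolded protein response and secretion, and Y-linked with Xist. Each list was tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, and adjusted over the 24 lists of a comparison. Named genes were 11 genes of the pathway and of bone, the 5 highest and 5 lowest folds past the criterion with a mean of at least 5 CPM and every mutant library on 1 side of the control mean, and the 1 or 2 members with the smallest p of lists. For the concordance they were up to 5 genes per class with the smallest larger adjusted p, and for the difference 5 of either sign with the smallest p. Of the genes named by this rule, 1 is not reported here.

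The tests were checked on simulated counts drawn from the real means and library sizes, with 200 changed genes spread over folds of 1.5, 2 and 4. For the Sik2/3 comparison, with 15479 genes, edgeR recovered 39.1%, 79.1% and 95.2% of genes changed by 1.5, 2 and 4-fold, and 3.5% of its calls were unchanged genes. For the C1HR comparison, with 13976 genes, it recovered 86.6%, 95.5% and 98.5%, with 4.1% unchanged among the calls. For the difference of effects, with 15387 genes, it recovered 34.8%, 73.1% and 90.8%, with 3.0% unchanged among the calls. A planted change of the osteoclast list was called in both comparisons, and 0 of 23 other lists were. The simulated genes were drawn independently of each other. Members of the real osteoclast list had an estimated correlation of 0.868 in the Sik2/3 comparison and 0.342 in C1HR. The check therefore cannot show how often camera with a preset correlation calls unchanged lists in the real data. Recovery with as many changed genes as were called in the real comparisons (8514 and 11787) was not simulated.

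Alternatives were DESeq2 size factors, DESeq2, limma voom with quality weights, the edgeR exact test, other filters on low counts, a fit of all groups, a replicate block, each library left out in turn, each choice of 6 of the 8 libraries labelled WT, the marrow, muscle and Y-linked scores as covariates, haemoglobin genes left out and glmTreat. Chosen after seeing the data were fits without the libraries labelled WT 5 and WT 6 or without C1HR 8 and C1HR 9, counts of similar labelled WT libraries summed, counts thinned to the smallest library, the labels of the Sik2/3 experiment exchanged, and the concordance with marrow or muscle covariates. For each result, 100 splits of the libraries into groups of the same sizes were fitted, the real split included.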

Results

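RNA from the cortical bone of mouse femurs was sequenced as 39 libraries in 2 experiments on mice with increased trabecular bone mass. The Sik2/3 experiment held 8 libraries labelled Sik2/3 DKO, after the removal of Sik2 and Sik3, salt-inducible kinases that act downstream of parathyroid hormone signalling, and 8 libraries labelled wild type (WT). The C1HR experiment held 12 libraries of col1a1-Pth1r H223R (C1HR) mice, which carry a constitutively active parathyroid hormone receptor under a type I collagen promoter, and 11 WT libraries of its own. Reads assigned to genes ranged from 22122742 to 23306853 in the libraries labelled DKO and from 20324595 to 24922490 in those labelled WT. They ranged from 14909609 to 16370874 in C1HR and from 11444686 to 13475805 in its WT group. The 10 most counted genes took a mean of 37.5% ± 3.55 of the gene counts in C1HR (SD, n = 12) and 15.8% ± 1.09 in its WT group (SD, n = 11). Col1a1 alone took 17.9% ± 3.18 in C1HR and 5.29% ± 1.08 in its WT group.

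On the first principal component of the Sik2/3 experiment, which held 63.3% of the variance, the libraries labelled DKO lay between -81.1 and -26.7. The libraries labelled WT 5 and WT 6 lay at -22.8 and -17.5, and the other 6 labelled WT between 60.1 and 101.8. On the first component of the C1HR experiment, with 83.8% of the variance, the WT libraries lay between -96.8 and -67.8. C1HR 8 and C1HR 9 lay at 19.4 and 10.7, and the other 10 C1HR libraries between 64.1 and 98.2.

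**Figure D1:**
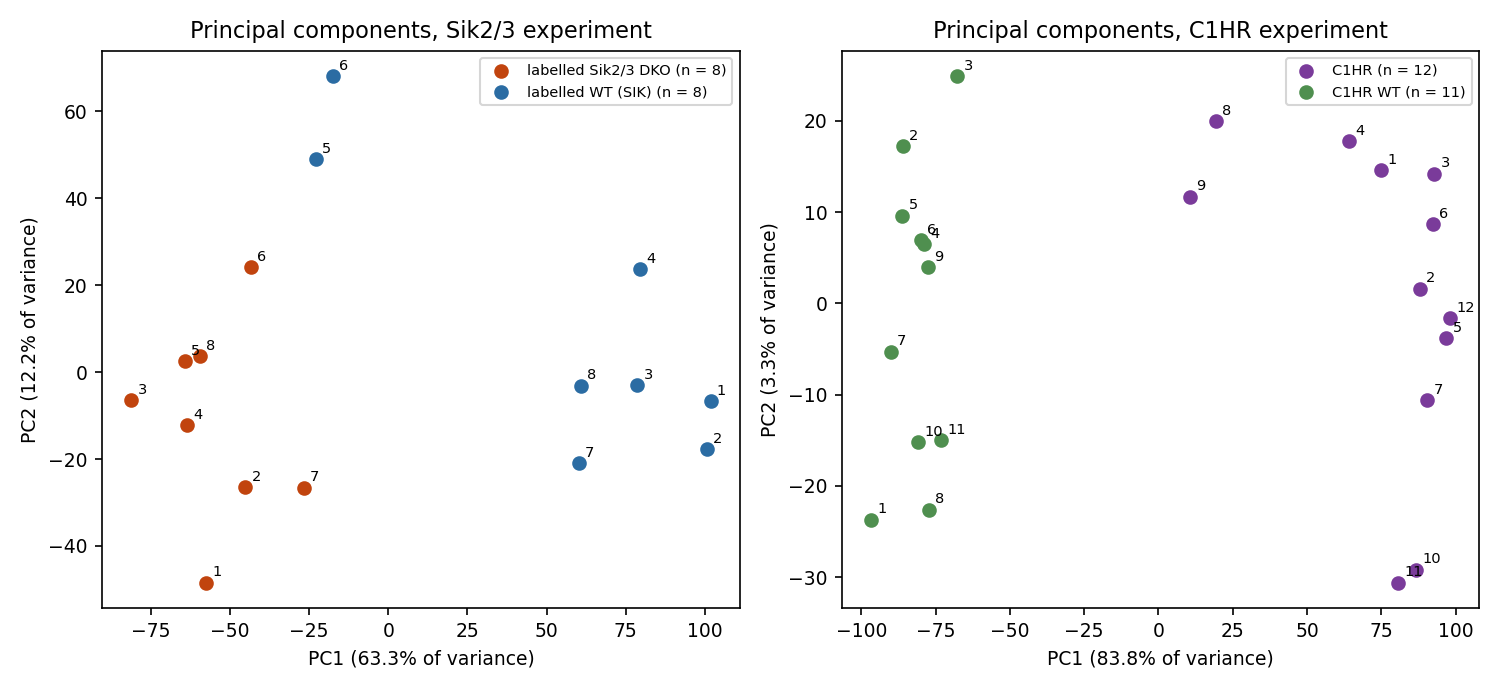
Scores of each library on the first 2 principal components of log2 CPM, for the Sik2/3 experiment (left) and the C1HR experiment (right); points are libraries, numbered as labelled, and axes give the share of variance. The libraries labelled WT 5 and WT 6, at -22.8 and -17.5 on the first component, lie next to those labelled DKO.

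Of the targeted genes, Sik2 went against the DKO label. Sik2 (ENSMUSG00000037112; chromosome 9, 50700917 to 50817178, mm9) measured 20.28 to 38.12 CPM in the 8 libraries labelled DKO, with a mean of 29.7 ± 6.60 (SD, n = 8), and 15.73 to 25.5 CPM in the 8 labelled WT, with a mean of 19.1 ± 3.20 (SD, n = 8). It was 1.56-fold higher in the libraries labelled DKO (log2 fold change 0.64, SE 0.14, edgeR quasi-likelihood adjusted p = 0.00127). Sik3 (ENSMUSG00000034135; chromosome 9, 45820903 to 46032277) measured 90.0 ± 15 CPM in the libraries labelled DKO and 104 ± 25.3 CPM in those labelled WT (log2 fold change -0.21, SE 0.14, edgeR adjusted p = 0.223). Sik1, the third member of the kinase family and not targeted, had a log2 fold change of -0.35 (SE 0.21, edgeR adjusted p = 0.161). Sik1 reached an adjusted p of 0.0386 without the libraries labelled WT 5 and WT 6, and limma voom with quality weights gave 0.0188 for Sik1 and 0.0134 for Sik3. Counts per gene pool all exons, so the loss of a deleted exon cannot be seen in them and only a lower level of the whole transcript could be. Exons of Sik2 overlap those of Ppp2r1b on the opposite strand, and the reads were counted without strand. Reads that match both are tallied as ambiguous and count for neither gene, and the effect of the overlap on the Sik2 values was not tested. Ppp2r1b, looked up after the values of Sik2 were seen, was also higher in the libraries labelled DKO (log2 fold change 0.76, SE 0.0768, edgeR adjusted p = 9.72e-06). Every direction given for the Sik2/3 experiment therefore compares libraries as labelled.

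**Figure D2:**
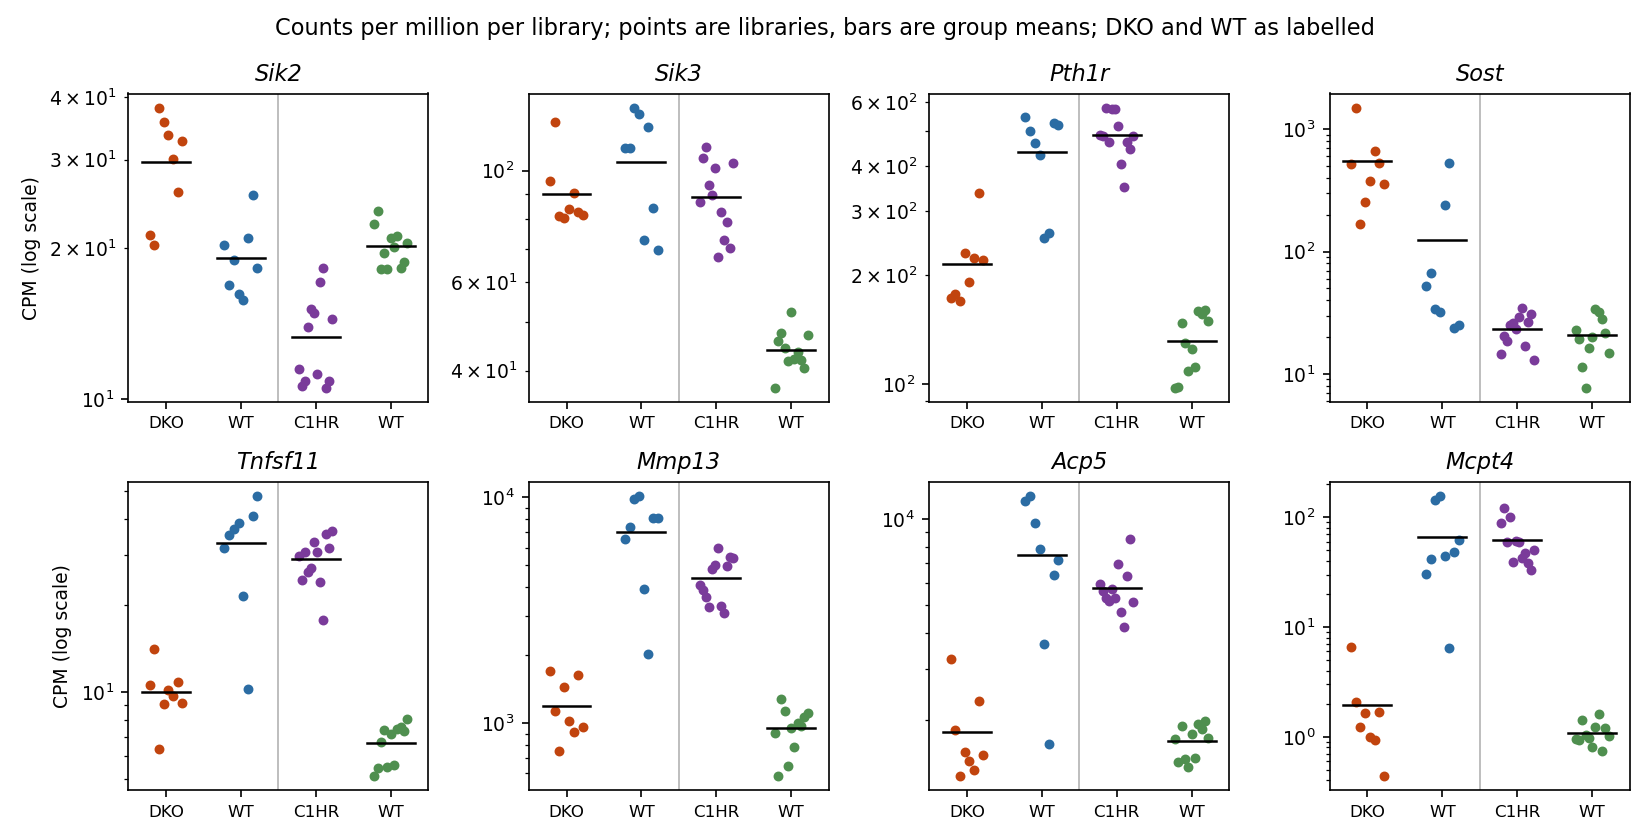
CPM per library on a log axis for Sik2, Sik3, Pth1r, Sost, Tnfsf11, Mmp13, Acp5 and Mcpt4 in the libraries labelled DKO and WT of the Sik2/3 experiment and in C1HR and its WT group; points are libraries and bars are group means. Sik2 is higher in the libraries labelled DKO (mean 29.7 CPM) than in those labelled WT (19.1 CPM).

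The comparison of libraries labelled DKO with those labelled WT asks what the loss of both kinases changes in cortical bone. Genes of bone resorption were lower in the libraries labelled DKO. Acp5 (ENSMUSG00000001348), the acid phosphatase of osteoclasts, was 4.11-fold lower, with 1820 ± 672 CPM against 7490 ± 3620 CPM (SD, n = 8 each; log2 fold change -2.04, SE 0.34, edgeR adjusted p = 0.000173). Mmp13, a collagenase of bone, was 5.86-fold lower (log2 fold change -2.55, SE 0.29, edgeR adjusted p = 1.8e-05), and Tnfsf11, which encodes the osteoclast differentiation factor RANKL, was 3.28-fold lower (-1.71, SE 0.24, 5.56e-05). Sost, which encodes the Wnt antagonist sclerostin, was 4.38-fold higher, with 550 ± 419 CPM against 125 ± 179 CPM (SD, n = 8 each; log2 fold change 2.13, SE 0.69, edgeR adjusted p = 0.0159). Called higher in the libraries labelled DKO by camera were the erythroid, granulocyte, B lineage, T and NK cell, megakaryocyte, cell cycle and interferon-stimulated lists. None of them was called with an estimated correlation (camera adjusted p = 0.301 for each).

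Of 15479 genes tested, 8514 (55%) passed an adjusted p under 0.05, of which 3726 were higher and 4788 lower in the libraries labelled DKO. At more than 2-fold, 1649 were higher and 1046 lower, 2695 together. Each gene named for this comparison that passed the test lay on the same side of the labelled WT mean in 8 of 8 libraries labelled DKO, except Tnfrsf11b with 7 of 8. For the genes named for the highest and lowest folds, the naming rule required this. Pth1r, the parathyroid hormone receptor (ENSMUSG00000032492; chromosome 9, 110624592 to 110649649), was 2.03-fold lower (log2 fold change -1.02, SE 0.19, edgeR adjusted p = 0.000326). Tnfrsf11b, the decoy receptor osteoprotegerin, was 1.88-fold lower (-0.91, SE 0.26, 0.00685). Col1a1 had a log2 fold change of -0.59 (SE 0.26, edgeR adjusted p = 0.0609) and Bglap, which encodes osteocalcin, 0.74 (SE 0.40, 0.125). Both depended on single libraries and on the tool. Col1a1 reached 0.0248, 0.00897 and 0.05 (under the threshold before rounding) without DKO 7, WT 5 and WT 6 in turn, and Bglap reached 0.025 without WT 6. With every library kept, both passed under limma voom with quality weights. Among genes over 5 CPM, the folds farthest from 0 were those of Oas3 (3.90, SE 0.58), Prss34 (3.33, SE 0.56), Hba-a2 (3.22, SE 0.79), Pyhin1 (3.15, SE 0.68) and Slc6a20a (3.15, SE 0.71) among the higher. Among the lower they were those of Fam5c (-5.67, SE 0.99), Tpsab1 (-5.20, SE 0.73), Mcpt4 (-5.09, SE 0.66), Tpsb2 (-4.97, SE 0.69) and Cma1 (-4.75, SE 0.64). Tpsab1, Tpsb2, Mcpt4 and Cma1 encode mast cell proteases. Mcpt4 averaged 1.95 CPM in the libraries labelled DKO and 66.7 CPM in those labelled WT. Hba-a2 has a near-identical copy, Hba-a1, and Tpsab1 resembles Tpsb2, so the split of reads within each pair is uncertain.

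In the osteoclast list, 14 of 15 members fell in the libraries labelled DKO and Itgb3 did not pass the test (median log2 fold change -1.90, camera adjusted p = 1.07e-06). The adjusted p was 0.301 with an estimated correlation. Tnfrsf11a, the receptor RANK, was 3.99-fold lower (log2 fold change -2, SE 0.31) and Mmp9, a gelatinase of osteoclasts, 4.17-fold lower (-2.06, SE 0.33). In the list of secreted factors that regulate osteoclasts, 6 of 7 tested members fell (median -1.08, camera adjusted p = 0.0184, and adjusted p = 0.301 with an estimated correlation), among them Csf1, a growth factor of the lineage (-1.19, SE 0.20). In the osteoblast list, 10 of 19 members fell and none rose (median -0.66, camera adjusted p = 0.00298, and adjusted p = 0.486 with an estimated correlation). Panx3, a channel protein (-2.20, SE 0.35), and Spp1, osteopontin (-1.82, SE 0.30), had the smallest p of that list. In the osteocyte list, 4 of 14 members rose and 2 fell, with a median of 0.19 and a camera adjusted p of 0.693. Sost, Fgf23, Kcnk2 and Dkk1, a Wnt antagonist (1.43, SE 0.35), rose, and Fam20c and Tnfrsf19 (-1.39, SE 0.22) fell. Of the matrix proteases and inhibitors, 10 of 14 fell, Mmp13 with the smallest p (median -1.15, camera adjusted p = 0.000177, and adjusted p = 0.301 with an estimated correlation). Of the fibrillar and pericellular matrix genes, 12 of 25 fell and Thbs1 rose (median -0.54, camera adjusted p = 0.012, and adjusted p = 0.506 with an estimated correlation). Col6a3 (-1.74, SE 0.26) and Col6a1 (-1.56, SE 0.26), chains of type VI collagen, had its smallest p.

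In the Wnt list, which holds targets and antagonists, 11 of 16 tested members fell and 3 rose (median -0.75, camera adjusted p = 0.0165, and adjusted p = 0.301 with an estimated correlation). The antagonists Sfrp4 (-2.42, SE 0.30) and Apcdd1 (-1.55, SE 0.23) and the target Axin2 (-0.90) fell, whereas the antagonists Sost and Dkk1 and the receptor gene Lgr5 (2.42) rose. In the list of cAMP and CREB-CRTC target genes, 10 of 20 tested members fell and Fgf23 rose (median -0.56, camera adjusted p = 0.00231, and adjusted p = 0.301 with an estimated correlation), with 11 fallen when adjusted over the list alone. Pde4d, a cAMP phosphodiesterase, had a log2 fold change of -0.89 (SE 0.12). In the immediate early and stress list, 8 of 14 members fell, Jun among them (-1.23, SE 0.16), and Zfp36 rose (median -0.70, camera adjusted p = 0.0165, and adjusted p = 0.301 with an estimated correlation). The immediate early list shares 4 members with the cAMP list.

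Markers of blood cell lineages rose in the libraries labelled DKO. In the erythroid list, 12 of 14 members rose (median 2.74, camera adjusted p = 3.76e-06), with Spnb1, a spectrin of red cells, at 1.49 (SE 0.31). In the granulocyte list, 15 of 16 rose, and 16 when adjusted over the list alone (median 2.18, camera adjusted p = 3.12e-07). Its member Ltf, lactoferrin, averaged 1730 CPM in the libraries labelled DKO and 279 CPM in those labelled WT. All 15 B lineage members rose (median 2.35, camera adjusted p = 1.07e-06), among them Blnk (1.61, SE 0.24). All 10 megakaryocyte members rose (median 2.39, camera adjusted p = 3e-05), among them the platelet glycoprotein gene Gp1ba (2.38, SE 0.48). In the T and NK cell list, 8 of 11 rose, and 9 when adjusted over the list alone (median 2.03, camera adjusted p = 0.000241), with Prf1, perforin, at 2.67 (SE 0.32). All 22 cell cycle members rose (median 1.70, camera adjusted p = 3.44e-16), among them Mcm3 (1.82, SE 0.20) and Plk1 (1.92, SE 0.23). All 14 interferon-stimulated members rose (median 2.11, camera adjusted p = 1e-08). For each of these 7 lists, the adjusted p was 0.301 with an estimated correlation. In the macrophage list, 4 of 11 tested members fell, and 3 when adjusted over the list alone (median -0.28, camera adjusted p = 0.489). In the skeletal muscle list, Actn3 fell, and no member when adjusted over the list alone (1 of 18; median -1.31, camera adjusted p = 0.254). Where no other count is given, adjustment over the list alone gave the same number of calls as over all genes.

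The erythroid, granulocyte and B lineage scores together predicted 68.2% of the variance of the group label. This measures how far scores and labels overlap, not a share of the expression change. With these scores as covariates, 2281 genes passed the adjusted p and 528 also the fold. Of 38 named genes that passed the test, 26 no longer did with these covariates, Acp5 (-0.42, adjusted p = 0.559), Tnfsf11 (-0.68, 0.177), Sost (0.79, 0.557) and Pth1r (-0.13, 0.63) among them, while Mmp13 (-1.25, 0.0413) and Mcpt4 (-3.89, 0.0192) still passed. Col1a1, not past the test, changed sign to 0.60. Of 15 lists called, cell cycle (median 0.61, camera adjusted p = 1.7e-08) and interferon-stimulated (0.74, 0.000796) were still called. The erythroid, granulocyte and B lineage lists make up these covariates, so the loss of their calls was largely built in. The same holds for any lost calls of their named members. The adipocyte (-1.01), skeletal muscle (-2.68) and endothelial (0.38) lists became called. Under a test against a fold of 2 (glmTreat), 648 genes passed. Sost rose by 3.04 without WT 6 (edgeR adjusted p = 0.000562) and by 3.86 without WT 5 and WT 6 (5.52e-06), and had 1.64 (0.0967) when the labelled WT libraries that resemble each other were summed in pairs. Hba-a2, Pyhin1 and Slc6a20a had 3.90, 3.79 and 3.92 without WT 5, and Tpsab1, Mcpt4 and Tpsb2 had -5.99, -5.70 and -5.71 without DKO 1.

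**Figure D3:**
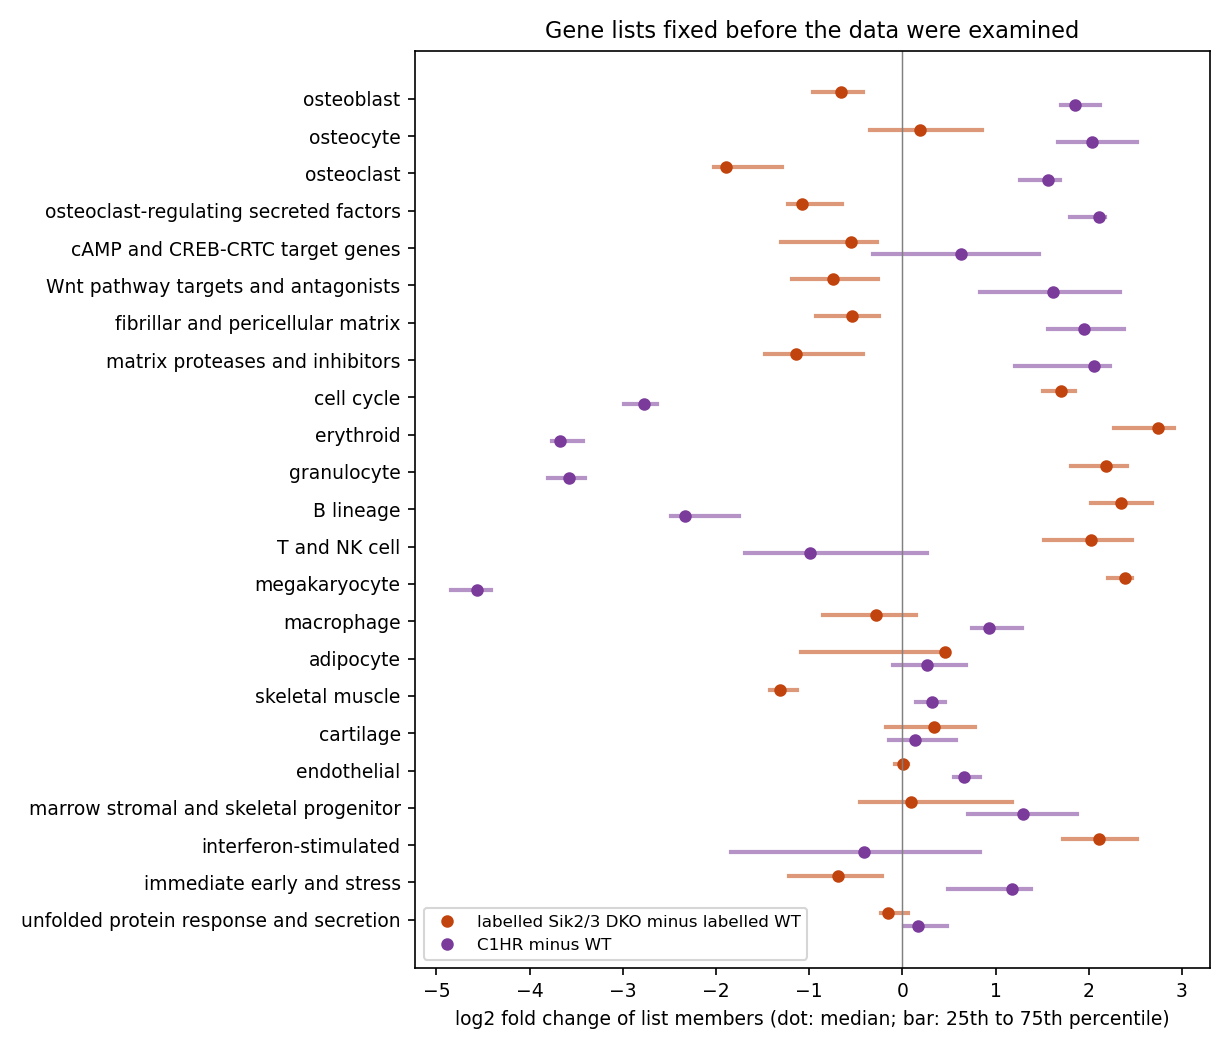
Log2 fold changes of the members of each gene list in the Sik2/3 experiment (libraries labelled DKO minus labelled WT) and in the C1HR experiment (C1HR minus WT); dots are medians and bars span the 25th to 75th percentile of members. The osteoclast list has a median of -1.90 in the former and 1.57 in the latter, and the cell cycle list 1.70 and -2.78.

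The comparison of C1HR with its WT group asks what constitutive parathyroid hormone receptor signalling in cells of the osteoblast lineage changes in bone. The osteoblast and osteoclast lists were called higher in C1HR by camera, and the erythroid, granulocyte, B lineage, megakaryocyte and cell cycle lists lower. None of them was called with an estimated correlation (camera adjusted p of 0.125 to 0.533). Spp1 was 8.02-fold higher, with 10000 ± 1950 CPM in C1HR (SD, n = 12) against 1250 ± 202 CPM in WT (SD, n = 11; log2 fold change 3.00, SE 0.11, edgeR adjusted p = 4.59e-17). Acp5 was 3.38-fold higher (1.76, SE 0.10, 2.26e-14), Tnfsf11 4.32-fold higher (2.11, SE 0.11, 3.84e-15) and Mmp13 4.64-fold higher (2.22, SE 0.14, 1.24e-13). Sost had a log2 fold change of 0.17 (SE 0.21, edgeR adjusted p = 0.461), with 23.2 ± 6.72 CPM in C1HR and 20.7 ± 8.19 CPM in WT.

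Of 13976 genes tested, 11787 (84.3%) passed an adjusted p under 0.05, of which 6109 were higher and 5678 lower in C1HR. At more than 2-fold, 3082 were higher and 2348 lower, 5430 together. Each gene named for this comparison that passed the test lay on the same side of the WT mean in 12 of 12 C1HR libraries, except Sik1 with 10 of 12. For the genes named for the highest and lowest folds, the naming rule required this. Pth1r was 3.70-fold higher (log2 fold change 1.89, SE 0.10, edgeR adjusted p = 8.68e-15), and counts per gene do not separate a transgene from the endogenous gene. Sik3 was 2.01-fold higher (1.01, SE 0.08, 2.04e-11), Sik1 1.33-fold higher (0.42, SE 0.09, 9.7e-05) and Sik2 1.52-fold lower (-0.60, SE 0.09, 1.47e-06). Ppp2r1b, which overlaps Sik2, was lower as well (-1.50, SE 0.117). Col1a1 was 4.55-fold higher (2.19, SE 0.14, 1.64e-13), Bglap 3.04-fold higher (1.60, SE 0.12, 2.91e-12) and Tnfrsf11b 5.12-fold higher (2.36, SE 0.10, 9.74e-17). Among genes over 5 CPM, the folds farthest from 0 were those of Tpsab1 (6.50, SE 0.30), Spock1 (6.05, SE 0.18), 1810041L15Rik (5.90, SE 0.30), Mcpt4 (5.82, SE 0.26) and the Wnt antagonist Sfrp2 (5.38, SE 0.39) among the higher. Among the lower they were those of Gp6 (-5.03, SE 0.47), Ly6g6f (-5.03, SE 0.42), Treml1 (-5.03, SE 0.50), Ppbp (-4.96, SE 0.73) and Tubb1 (-4.90, SE 0.56). Gp6, Ppbp and Tubb1 are also members of the megakaryocyte list. Gp6 had -5.63 without C1HR 8.

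All 19 members of the osteoblast list rose in C1HR (median log2 fold change 1.86, camera adjusted p = 1.45e-09, and adjusted p = 0.125 with an estimated correlation), with the transcription factor gene Runx2 at 2.17 (SE 0.09). In the osteocyte list, 12 of 13 tested members rose and Sost did not pass the test (median 2.04, camera adjusted p = 7.32e-07, and adjusted p = 0.125 with an estimated correlation). Kcnk2 (2.88, SE 0.12) and Irx5 (2.09, SE 0.09) had its smallest p. In the osteoclast list, 14 of 15 members rose and Itgb3 fell (median 1.57, camera adjusted p = 2.36e-06, and adjusted p = 0.129 with an estimated correlation), with Atp6v0d2, a proton pump subunit, at 1.60 (SE 0.07) and Tnfrsf11a at 1.93 (SE 0.11). All 7 tested secreted factors that regulate osteoclasts rose (median 2.11, camera adjusted p = 0.000121, and adjusted p = 0.125 with an estimated correlation), among them Sema3a (1.62, SE 0.08). In the Wnt list, 13 of 16 tested members rose and Lgr5 fell (median 1.61, camera adjusted p = 5.59e-05, and adjusted p = 0.125 with an estimated correlation). Nkd2 (2.51, SE 0.10) and the antagonist Sfrp4 (2.34, SE 0.09) had its smallest p. Of the fibrillar and pericellular matrix genes, 23 of 25 rose, Lum (1.66, SE 0.06) and Dcn (1.57, SE 0.06) among them, and Thbs1 fell (median 1.95, camera adjusted p = 7.61e-10, and adjusted p = 0.125 with an estimated correlation). Of the matrix proteases and inhibitors, 12 of 13 tested rose, with Mmp2 at 2.34 (SE 0.09; median 2.05, camera adjusted p = 2.36e-06, and adjusted p = 0.125 with an estimated correlation). In the list of cAMP and CREB-CRTC target genes, 12 of 19 tested members rose and 5 fell (median 0.63, camera adjusted p = 0.178), with Nr4a2, an orphan nuclear receptor gene, at 2.19 (SE 0.10). In the marrow stromal and skeletal progenitor list, 12 of 14 members rose and 2 fell (median 1.30, camera adjusted p = 0.000179, and adjusted p = 0.211 with an estimated correlation), with Grem1, a BMP antagonist, at 3.87 (SE 0.09). In the macrophage list, 9 of 10 tested members rose and Cd5l fell (median 0.92, camera adjusted p = 0.0364, and adjusted p = 0.446 with an estimated correlation), with Csf1r at 1.62 (SE 0.09). In the immediate early and stress list, 10 of 13 tested members rose, Jun (1.62, SE 0.08) among them, and Dusp1 fell (median 1.18, camera adjusted p = 0.0316, and adjusted p = 0.443 with an estimated correlation).

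Markers of the erythroid, granulocyte, B and megakaryocyte lineages fell in C1HR. All 14 erythroid members fell (median -3.68, camera adjusted p = 0.00478, and adjusted p = 0.533 with an estimated correlation), with Hba-a2 at -3.43 (SE 0.38). All 16 granulocyte members fell (median -3.58, camera adjusted p = 0.000449, and adjusted p = 0.469 with an estimated correlation), with Ly6g at -3.79 (SE 0.36). In the B lineage list, 14 of 15 fell and Ebf1 did not pass the test (median -2.34, camera adjusted p = 0.000206, and adjusted p = 0.443 with an estimated correlation), with Fcrla at -2.76 (SE 0.21). All 10 megakaryocyte members fell (median -4.57, camera adjusted p = 0.000659, and adjusted p = 0.446 with an estimated correlation), with Pf4 at -3.64 (SE 0.20). All 22 cell cycle members fell (median -2.78, camera adjusted p = 7.03e-07, and adjusted p = 0.443 with an estimated correlation), with Tyms at -2.33 (SE 0.20) and Cdk1 at -2.66 (SE 0.23). In the interferon-stimulated list, 4 of 12 tested members rose and 7 fell (median -0.41, camera adjusted p = 0.196). None of the 18 skeletal muscle members passed the edgeR test (median 0.32, camera adjusted p = 0.899). Adjustment over each list alone gave the same counts as over all genes. None of the 15 lists called in either comparison was called with an estimated correlation.

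The 3 blood lineage scores predicted 88.4% of the variance of the group label, C1HR or WT, which is not a share of the expression change. With these scores as covariates, 4976 genes passed the adjusted p and 2275 also the fold. Of 42 named genes that passed the test, 10 no longer did with these covariates, among them Sik1, Sik2, Gp6 and Hba-a2 and also Ppbp (0.46, adjusted p = 0.357) and Tubb1 (0.05, 0.916), which changed sign. The osteoblast (17 of 19 members, median 1.55), osteocyte (12 of 13, 1.55) and osteoclast (14 of 15, 1.14) lists were still called, and the erythroid, granulocyte, B lineage, macrophage and immediate early lists were not. Since the erythroid, granulocyte and B lineage lists make up these covariates, the loss of their calls was largely built in, as for their member Hba-a2. The erythroid list turned to a median of 0.75 (7 up and 3 down of 14), the endothelial list became called (camera adjusted p = 0.0398), and the cell cycle (-0.72, 11 of 22 down) and megakaryocyte (-0.33, 3 of 10 down) lists stayed called.

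The shared and opposite changes of the 2 models are the focus that the series gives. Of 13821 genes tested in both comparisons, 21 passed the adjusted p and 2-fold thresholds in both in the same direction, and 1892 in opposite directions (98.9% of those called in both). Lists of these sizes drawn independently would share 450.2 genes in the same direction and 419.5 in opposite directions. Without the library labelled WT 6 the count in the same direction was 42, without the libraries WT 5, WT 6, C1HR 8 and C1HR 9 it was 63, and with marrow covariates it was 10 beside 65 in opposite directions. Across genes, which are not independent replicates, the log2 fold changes had Pearson r = -0.78 and Spearman rho = -0.753, and Pearson r = -0.169 with the marrow covariates. The comparisons share no control libraries, and the direction of the Sik2/3 effects rests on the labels. Sik2 went against these labels, but it also changed in C1HR (log2 fold change -0.60), where it was not targeted. With the labels of the Sik2/3 experiment exchanged, 1892 genes would be called in the same direction and 21 in opposite directions, with r = 0.78. At an adjusted p alone, 536 genes changed in the same direction and 6517 in opposite directions.

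The genes in opposite directions with the smallest larger adjusted p were Pde7b, a cAMP phosphodiesterase (-1.87 in the libraries labelled DKO and 2.52 in C1HR), Fgf7 (-1.74 and 2.40), Pml (1.02 and -1.35), Camk4 (-2.04 and 2.86) and D0H4S114 (-1.30 and 1.82). Of the genes in the same direction, 17 rose and 4 fell. Among those that rose were Oasl2, an interferon-stimulated gene (1.97, SE 0.26 and 1.18, SE 0.13), Siglec1, a macrophage lectin (1.35, SE 0.28 and 1.56, SE 0.15), D14Ertd668e (1.02, SE 0.22 and 1.04, SE 0.17), Papln (1.39, SE 0.31 and 1.73, SE 0.22) and Grm4, a glutamate receptor (2.81, SE 0.62 and 2.61, SE 0.17). Grm4 was above the labelled WT mean in 6 of 8 libraries labelled DKO. The genes that fell in both were Artn (-1.31, SE 0.32 and -1.33, SE 0.18), Trim15 (-1.79, SE 0.44 and -1.21, SE 0.23), Cfd (-1.41, SE 0.44 and -1.51, SE 0.42) and C2cd4a (-1.03, SE 0.38 and -1.47, SE 0.20). Single libraries decided some of these places. In the Sik2/3 comparison Cfd had -0.84 without WT 5, and C2cd4a had adjusted p of 0.0508, 0.0566, 0.0564 and 0.0535 without DKO 1, 2, 5 and 8 and of 0.0529, 0.057, 0.0726 and 0.0759 without WT 1, 2, 7 and 8. D14Ertd668e was under 2-fold there without DKO 3, 4, 6 or 7 or WT 1, 2, 3 or 4 (0.92 to 0.997), and in the C1HR comparison without C1HR 10 or 11 or C1HR WT 1 or 9 (0.975 to 0.998), and Pml without DKO 3 (0.97) or DKO 5 (0.997). With marrow covariates none of these 9 genes in the same direction passed both thresholds in both comparisons. Group means were low for Papln (0.447 to 3.95 CPM), Trim15 (0.464 to 2.03 CPM) and C2cd4a (0.533 to 1.97 CPM). Dkk1 rose in both (1.43, SE 0.35 and 1.33, SE 0.13), and its effects did not differ (difference 0.16, SE 0.34, edgeR adjusted p = 0.671).

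**Figure D4:**
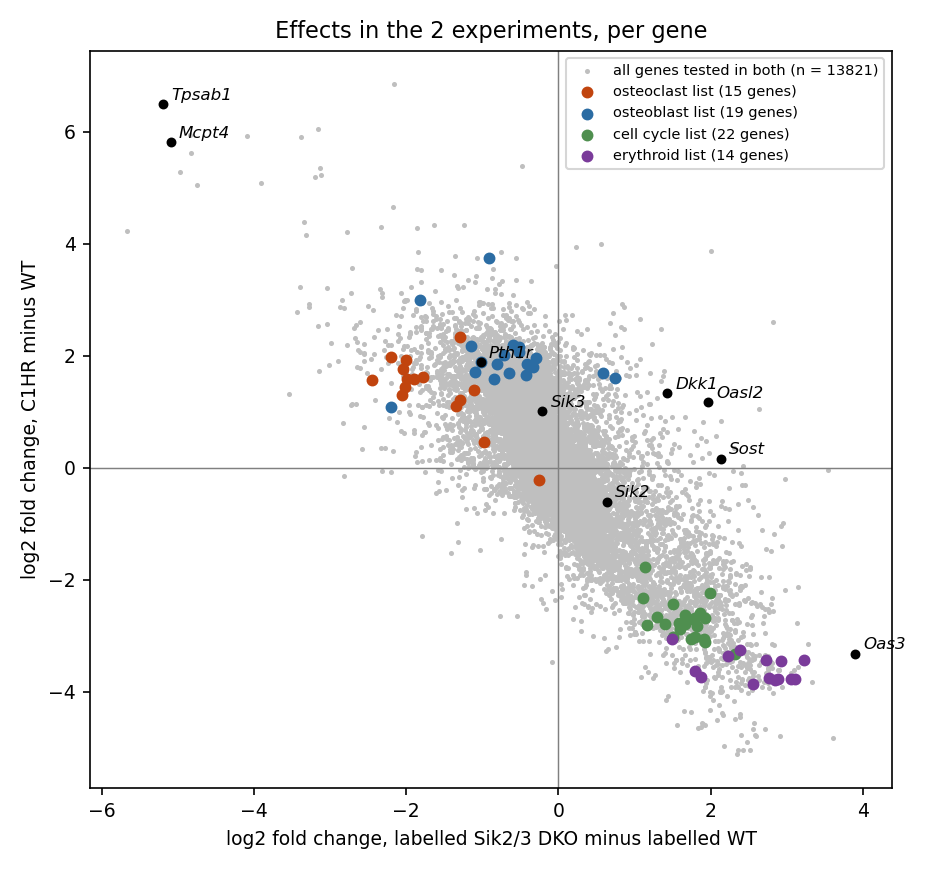
Log2 fold change of each of 13821 genes tested in both experiments, libraries labelled DKO minus labelled WT (horizontal) and C1HR minus WT (vertical); coloured points are members of 4 gene lists and black points are named genes. The correlation across genes is -0.78, with the osteoclast and osteoblast lists in the upper left and the cell cycle and erythroid lists in the lower right.

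The difference of the 2 effects, labelled DKO minus labelled WT less C1HR minus WT, was tested in 1 fit of all 39 libraries, in which 12336 of 15387 genes (80.2%) passed an adjusted p under 0.05. The difference was positive for 5866 genes and negative for 6470. With the labels of the Sik2/3 experiment exchanged, 8703 genes passed. The smallest p among positive differences were those of H2afy (2.55, SE 0.13), Pgd (2.28, SE 0.12), Arrb2 (2.94, SE 0.15), Rad9 (2.07, SE 0.11) and Parp1 (1.92, SE 0.10). Among negative differences they were those of Smoc2 (-3.45, SE 0.16), D0H4S114 (-3.05, SE 0.14), Pde7b (-4.33, SE 0.20), Fgfr2 (-3.59, SE 0.17) and Cpxm1 (-3.80, SE 0.19). Exons of Rad9 and Fgfr2 overlap other genes. Among the genes of the pathway, the difference was -2.85 for Pth1r (SE 0.20), 1.30 for Sik2 (SE 0.16), -1.16 for Sik3 (SE 0.16), -3.76 for Tnfsf11 (SE 0.25) and 2.03 for Sost (SE 0.65, edgeR adjusted p = 0.00463). The osteoclast list had 14 of 15 members with a negative difference past the test (median -3.38, camera adjusted p = 1.03e-05, and adjusted p = 0.379 with an estimated correlation). All 19 osteoblast members had a negative difference past the test (median -2.60, camera adjusted p = 6.93e-07, and adjusted p = 0.284 with an estimated correlation), and all 22 cell cycle members a positive one (median 4.53, camera adjusted p = 2.08e-10, and adjusted p = 0.379 with an estimated correlation). Other lists with a negative difference by camera were osteocyte (11 of 14 negative and 2 positive; median -1.77, adjusted p = 0.0109), secreted factors that regulate osteoclasts (6 of 7; -3.20, 0.000846) and Wnt (13 of 16, with Sost and Lgr5 positive; -2.34, 0.000273). The matrix genes (23 of 25; -2.30, 6.93e-07) had Thbs1 positive, with 2 positive when adjusted over the list alone, and the matrix proteases (12 of 13; -3.32, 1.03e-05) had none. The cAMP list (12 of 20 negative and 4 positive; -1.36, 0.0408), the stromal list (10 of 14 and 3; -0.99, 0.048) and the immediate early list (11 of 14 and 2; -1.75, 0.0132) were negative as well. Positive by camera were erythroid (14 of 14; 6.48, 0.00071), granulocyte (16 of 16; 5.69, 4.14e-05), B lineage (15 of 15; 4.59, 0.000163), T and NK cell (10 of 11, with Cd4 negative; 3.50, 0.0441), megakaryocyte (10 of 10; 7.08, 0.000273) and interferon-stimulated (13 of 14; 2.32, 0.00297). With an estimated correlation, none of the 17 lists was called (adjusted p of 0.284 to 0.453). Not called were macrophage (7 of 11 negative and 2 positive; -1.09, 0.148), adipocyte (2 of 10 negative and 2 positive; 0.07, 0.731) and skeletal muscle (2 of 18 negative and 0 over the list alone; -1.60, 0.456). Nor were cartilage (3 of 17 negative and 3 positive, 1 positive over the list alone; 0.27, 0.855) and endothelial (12 of 14 negative and 2 positive; -0.68, 0.236). The same held for the unfolded protein response (8 of 16 negative, 7 over the list alone, and 2 positive; -0.24, 0.389) and Y-linked with Xist (0 of 5; 0.48, 0.855). The libraries of the 2 experiments differ in size, and whether they were made together is not stated in the labels.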

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

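The counts over other splits of the libraries were fixed before the results were seen, and the tests of the 3 weighed patterns were chosen after the results were seen, as were the results with exchanged labels and the choice of genes for which differences between experiments are listed.

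As labelled, the effects of the 2 experiments ran in opposite directions (r = -0.78), with osteoclast genes lower in the libraries labelled DKO and higher in C1HR. Exchanged group labels in the Sik2/3 experiment would put the lower Sik2 and Sik3 levels in the libraries labelled WT, and the log2 fold change of Sik2 was 0.64 and that of Sik3 -0.21. Sik2 also fell in C1HR (log2 fold change -0.60), where it was not targeted, and was no longer called there with the marrow covariates. Gene counts do not show deleted exons, so exchanged and correct labels cannot be told apart. Exons of Sik2 also overlap those of Ppp2r1b on the opposite strand, and the effect of this overlap on the Sik2 values was not tested. With exchanged labels r would be 0.78, with 1892 genes in the same direction and 21 in opposite directions. If more marrow left in the libraries labelled DKO lowered every bone cell type alike, the osteoclast and osteocyte scores would fall together. The osteoclast score less the osteocyte score differed by -1.78 (two-sided exact permutation test, p = 0.00233, 12870 groupings). This argues against such an even lowering as the whole cause for osteoclast genes, but whether marrow lowers both scores alike was not tested. The marrow scores predict 68.2% of the variance of the group label, which is not a share of the expression change. With these scores as covariates, the osteoclast list had a median of -0.25 in place of -1.90 (0 of 15 members past the test, camera adjusted p = 0.977), and r over all genes was -0.169. A part played by marrow stays open, marrow and genotype cannot be told apart over all genes, and the genotype is untested.

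The libraries labelled WT 5 and WT 6 lay with those labelled DKO on the first principal component, and the design text counts 6 WT samples where the labels give 8. Marrow left in these libraries could place them there. Their osteocyte score stood at least 0.69 higher against their osteoblast score than in any of the other 6, whose range was 0.27. If marrow lowers both scores alike, which was not tested, this argues against marrow as the whole cause. An exchange with a pair of libraries labelled DKO needs partners out of place, and 0 of 8 libraries labelled DKO reached the other 6 labelled WT. Wrong labels on these alone stay open, since 1 of the 2 had Sik2 below the lowest library labelled DKO (20.28 CPM) and the other did not, so that wrong and right labels cannot be told apart. The osteocyte score less the osteoblast score of WT 5 and WT 6 (-2.81 and -2.51) lay within the range of the libraries labelled DKO (-2.96 to -1.45). On the second component WT 5 and WT 6 stood at 49 and 68.1, above all other libraries of the experiment. Without them the median of the muscle list was 0.08 in place of -1.31, and a part played by muscle was not tested. Nor was a difference in genotype or in the animals tested.

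Osteoblast genes were higher in C1HR than in its WT group. A lower share of marrow cells may raise them, and with the 3 marrow scores as covariates the osteoblast score was 1.67 higher on the log2 scale (SE 0.17, n = 23 libraries). On the CPM scale, on which shares of RNA add up, it was 270.4 CPM higher with these scores (SE 129.9, p = 0.0519), beside 869.7 CPM (SE 38.4) without. As the scores predict 88.4% of the variance of the group label, a lower marrow share and the C1HR genotype, which stays open and untested, cannot be told apart. For a difference in library size, counts were thinned to equal totals. The osteoblast list then had a median log2 fold change of 1.87 (19 of 19 members rose, camera adjusted p = 1.65e-09), beside 1.86. Thinning keeps the expected share of each gene, so this outcome was near certain and does not decide the question. Without thinning, camera gave the list an adjusted p of 0.125 with an estimated correlation.

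Other splits of the libraries gave smaller counts than the labels did, which argues against chance as their source. The splits treat libraries as exchangeable, and 1 of 100 is the smallest share they can give. They cannot tell genotype from another difference between the labelled groups, such as marrow. The real split was the 1 of 100 with a result as large for each. In the Sik2/3 comparison the highest other counts were 2512 beside 8514 genes and 722 beside 2695, in a split that kept 7 of the 8 libraries labelled DKO together. In the C1HR comparison they were 8361 beside 11787 and 1942 beside 5430, in a split with 3 of the 12 C1HR libraries in the C1HR arm, close to the mirror of the real one. For the difference of effects the highest other count was 9 beside 12336. For the correlation the farthest in the negative direction was -0.69 beside -0.78, and the other 99 joint splits ranged from -0.69 to 0.686, so they alone give wide values of either sign.

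Single libraries far from the rest of their group appeared in 20 of 190 groups of values tested, where 9.5 are expected by chance. These groups held libraries labelled DKO or labelled WT, and C1HR and its own WT group were not tested in this way. Whether the values meet the assumptions behind the expected number was not tested. Values of different genes in the same library can also vary together. The library labelled DKO 1 was highest for Cma1 (4.73 CPM), Hba-a2 (2156 CPM), Mcpt4 (6.64 CPM), Mmp9 (2145 CPM), Tpsab1 (9.88 CPM) and Tpsb2 (11.9 CPM). DKO 2 was highest for Sik3 (124.9 CPM), Sost (1509 CPM) and Tnfrsf11b (84.2 CPM), DKO 6 for D0H4S114 (107.2 CPM), and DKO 7 for Apcdd1 (74.0 CPM) and Pth1r (337.2 CPM). The library labelled WT 5 was highest for Cfd (39.5 CPM), Pyhin1 (8.52 CPM), genes with a count (22765) and the share of reads not mapped uniquely (41.2%). It was lowest for the ambiguous share (1.36%), the total of which includes the reads not mapped uniquely. WT 6 was highest for Dkk1 (65.0 CPM), Sost (531 CPM) and the osteocyte score (7.00 on the log2 scale).

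The 2 experiments differed in their effects, by a test of the difference, for 12336 genes as labelled and for 8703 with the labels of the Sik2/3 experiment exchanged. The log2 differences, Sik2/3 effect minus C1HR effect, were -0.70 for Sik1, 1.30 for Sik2, -1.16 for Sik3, -2.85 for Pth1r, 2.03 for Sost, -3.76 for Tnfsf11, -3.20 for Tnfrsf11b, -4.70 for Mmp13, -2.71 for Col1a1, -0.80 for Bglap and -3.73 for Acp5. They were 2.55 for H2afy, 2.28 for Pgd, 2.94 for Arrb2, 2.07 for Rad9, 1.92 for Parp1, -3.45 for Smoc2, -3.05 for D0H4S114, -4.33 for Pde7b, -3.59 for Fgfr2 and -3.80 for Cpxm1. In read tallies that the comparisons do not use, the median share of reads that matched more than 1 gene was 1.885% in C1HR, above the highest of its WT libraries (1.43%). The total of this share includes reads not mapped uniquely, with medians of 29.7% in C1HR and 48.7% in its WT group. It therefore does not show more such reads among those mapped uniquely.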

How the results depend on the processing

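The fits without libraries that stand apart, with summed or thinned counts or exchanged labels, the alternatives of genes named for the concordance, and the concordance with marrow or muscle covariates were chosen after the data were seen. Counts stayed within 1.5 times their value under the other scalings, tools and filters not named here. With the marrow covariates, 2281 genes in place of 8514 passed the adjusted p in the Sik2/3 comparison and 528 in place of 2695 both thresholds, and 4976 in place of 11787 and 2275 in place of 5430 in the C1HR comparison. In C1HR, Ppbp and Tubb1 turned to 0.458 and 0.048, neither past the test. Over both comparisons, 36 of 80 named-gene calls were lost with these covariates, among them Hba-a2 in C1HR, whose own list gives a covariate. Testing against a fold of 2 (glmTreat), a stricter hypothesis, gave 648 genes in the Sik2/3 comparison. The 21 genes in the same direction became 47 with no filter on low counts, 60 with limma voom, 8 with a mean of at least 5 CPM in both, which tests fewer genes, 536 at an adjusted p alone, 63 without the libraries that stand apart, 10 with marrow covariates and 37 with the muscle covariate. The 1892 in opposite directions became 6517 at an adjusted p alone and 65 with marrow covariates, and the correlation of -0.78 became -0.577 with no filter and -0.169 with marrow covariates. With the labels of the Sik2/3 experiment exchanged, which turns the sign of its effects, 1892 genes were in the same direction and 21 in opposite directions, r was 0.78, and the difference of effects had 8703 genes in place of 12336. Apart from this turn and the thresholds, the cause of these shifts, those with the marrow covariates included, was not tested. Leaving out 1 library at a time gave 7845 to 9390 and 2523 to 3108 genes in the Sik2/3 comparison, 11604 to 11821 and 5292 to 5539 in C1HR, 12235 to 12482 for the difference, 15 to 42 in the same direction, 1763 to 2142 in opposite directions and r of -0.796 to -0.759. Leaving out 2 of the 8 libraries labelled WT gave 7155 to 10085 genes, with a median of 7797.5, the highest without WT 5 and WT 6. Replicate numbers gave no clear pairing: residual correlations of equal numbers had medians of 0.136 and -0.08, 5 of 8 and 4 of 11 were over 0.1, and 2 of 8 and 2 of 11 libraries correlated best with their own number. With the replicate block, 8422 and 2842 genes passed in the Sik2/3 comparison and 11506 and 5325 in C1HR. Of 8514 and 11787 gene calls, 7927 and 11436 were shared with the block. Among named genes and lists as a whole, the block changed the calls of Bglap (adjusted p = 0.0266), the muscle list (0.0146) and, in C1HR, the macrophage list (0.0739). An estimated correlation ended 30 of 30 list calls. Fry, which does not compare members with other genes, called each of these lists, such as osteoclast in the Sik2/3 comparison (fry adjusted p = 0.000679). In C1HR it also called lists that camera did not, among them cAMP (fry adjusted p = 2.99e-11) and interferon-stimulated (2.59e-08). Haemoglobin genes were left out without mitochondrially encoded ones, which the files lack. At 1.5-fold, 39.1% of simulated changes were recovered in the Sik2/3 comparison, so smaller changes can be missed.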

Other observations

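Several gene lists fixed before the data were examined were not called by camera in 1 or both comparisons. In the endothelial list, 2 of 14 members rose and 1 fell in the libraries labelled DKO (median 0.01, camera adjusted p = 0.683), and none of the fallen held when adjusted over the list alone. In C1HR, 12 of 14 endothelial members rose and Stab2, a receptor of sinusoidal endothelium, fell (-1.74; median 0.66, camera adjusted p = 0.0659). In the T and NK cell list, 1 of 9 tested members, Cd4 (1.89), rose in C1HR and 5 fell (median -0.99, camera adjusted p = 0.247). In the adipocyte list, 2 of 10 tested members rose and 3 fell in the libraries labelled DKO, with a median of 0.45, a mean of -0.09 and an upward test (camera adjusted p = 0.378), and 3 of 9 rose and 1 fell in C1HR (median 0.27, camera adjusted p = 0.863). The adipocyte list was called upward without the libraries labelled WT 5 and WT 6, a fit chosen after the data were seen (camera adjusted p = 0.00499). In the cartilage list, 1 of 14 tested members, Col9a3 (1.43), rose in the libraries labelled DKO (median 0.34, camera adjusted p = 0.683) and 4 of 17 rose in C1HR (median 0.13, camera adjusted p = 0.823), with Prg4 at 3.74 and Col11a2 at 2.31. In the marrow stromal and skeletal progenitor list, 3 of 14 rose and 5 fell in the libraries labelled DKO (median 0.09, camera adjusted p = 0.885). It was called upward without WT 5 and WT 6 (camera adjusted p = 0.00499).

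In the list of the unfolded protein response and secretion, 1 of 16 members rose and 3 fell in the libraries labelled DKO (median -0.15, camera adjusted p = 0.683), and 7 rose and 2 fell in C1HR (median 0.17, camera adjusted p = 0.418). Creb3l1, a transcription factor of secretory load, had log2 fold changes of -1.08 and 2.06. None of the 5 genes of the Y-linked and Xist list passed the edgeR test in either comparison (camera adjusted p = 0.683 and 0.863). Ddx3y exceeded Xist in 6 of 8 libraries labelled DKO, 4 of 8 labelled WT, 6 of 12 C1HR and 5 of 11 C1HR WT libraries. Some libraries of the C1HR experiment held reads of both genes, such as C1HR 2 with 30.05 CPM of Ddx3y and 2.69 CPM of Xist and C1HR 3 with 2.08 and 70.2 CPM. The labelled WT libraries 1 and 2, 3 and 4, and 7 and 8 resembled each other most, with chi-square per degree of freedom of 7.37, 17.97 and 18.26 beside a median of 59.4 over 28 pairs. With these pairs summed, 6691 genes in place of 8514 passed the adjusted p. Close pairs in C1HR included 1 and 4 (4.61), 5 and 6 (6.14) and 8 and 9 (8.55), beside a median of 47.8 over 66 pairs. Whether such pairs come from the same animal is not stated in the labels, and each library was treated as a replicate. Hba-a2 averaged 3.95 CPM in the C1HR WT libraries and 835 CPM in the libraries labelled DKO, while its near-identical copy Hba-a1 took 1.37% of the counts in the C1HR WT libraries.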
